A study of Homo sapiens with 3 samples.

How the data were processed

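Transcripts of CD4+CD25+ T cells from the blood of 3 healthy donors were measured by droplet single-cell RNA sequencing (10x Chromium 3′ chemistry, version 2, Illumina HiSeq). Per the labels, the authors processed the reads with Cell Ranger. Its version, the genome build and the annotation are not given in the sources used here. The deposited table holds raw UMI counts per gene and cell barcode, and it was checked to hold whole numbers only. It pools 15362 genes and 2973 barcodes, every gene occurs in at least 3 barcodes, and the barcode with the fewest genes has 223. Column names end in a suffix of 1, 2 or 3, which separates as many libraries as there are samples, but no label ties a suffix to a donor. Each library was read as 1 donor and 1 replicate, and donor numbers were not used. The plan was to run no test if cells could not be tied to donors, and the tests rest on this reading. If the suffixes were not donors, the p values would describe the spread between libraries alone. The reads and any other file of the series were not used here.

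For the privacy of the donors, 119 genes were left out of doublet calling, clustering and the tested sums (0.167% of UMIs). These were sex-linked marker genes, HLA-DQ and HLA-DRB, T cell receptor and immunoglobulin segments, and common deletion genes. They stayed in the UMI and gene totals per cell, the matching, the thinning and the comparison of copies with originals. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept (2278 cells). Scrublet, run per library with an expected rate of 0.01, called 32 doublets (1.40%, score thresholds 0.077, 0.0459 and 0.0701), and 2246 cells remained. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen, the library mean of each gene was removed, and 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 gave 7 clusters. A cluster was named after the class with most markers at least 1.5 times higher than in the other cells (20 CPM added to both) and detected in at least 10% of its cells, with at least 3 markers, and a tie went to the class listed first. A cluster whose cells had a median under 1/3 of the median UMIs of their library, with no marker of the class among its top 10 genes, stayed unnamed. This applied to cluster 5 (0.302) and not to cluster 1 (0.389), which had no such marker among its top genes either. Shares of cells are means and SD over libraries, and intervals are exact 95% binomial intervals, which cover counting error alone, as do upper limits from a count of 0 (3 counts).

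A gate split cells by at least 1 UMI of a gene against 0. Positive and zero cells were matched 1 to 1 on total UMIs within each library (20 quantile bins, seed 1), since a deeper cell is likelier to show a UMI. UMI counts were summed per library and class and tested with edgeR (TMM, filterByExpr with a minimum count of 10, robust quasi-likelihood fit, library as a block, two-sided, Benjamini-Hochberg adjusted p under 0.05). The gates were FOXP3 in all cells, HLA-DRA and CCR7 in FOXP3-positive cells, and the difference of the HLA-DRA effect between FOXP3-positive and FOXP3-zero cells (4 sums per library). The gate gene has 0 UMIs in its zero class by construction and was left out of counts and lists. Log2 fold changes are positive over zero cells. The median over all tested genes was 0.01, 0.02, -0.01 and -0.01 in the 4 comparisons. Self-tests on simulated data, in which 200 genes were changed, recovered 83.6%, 61.2%, 82.1% and 37.3% of 2-fold changes in the FOXP3, HLA-DRA, CCR7 and interaction comparisons, and 32.8%, 28.4%, 49.3% and 5.97% of 1.5-fold changes. Across genes, positive and zero sums were checked to correlate within a library (r = 0.185 to 0.354) more than between libraries; genes are not independent replicates.

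Gene lists were tested with camera (preset correlation 0.01, at least 3 tested members, adjusted over the lists of a gate) and again with an estimated correlation. With an estimated correlation no list passed in any gate. The lists were Treg core, conventional T, naive and central memory, effector memory, MHC class II, homing receptors, cytotoxic and Th1, Th2 and Th17, interferon response, cell cycle, immediate early and stress, glycolysis, ribosomal proteins, mitochondrial genes, and markers of B cells, monocytes, NK cells, CD8 T cells, dendritic cells, platelets and red cells. Named genes are the 10 largest rises and 10 largest falls past the threshold with an average log2 CPM of at least 5 and the same sign in 3 libraries, up to 5 each way for the interaction, and up to 4 members per list with the smallest p. Ribosomal protein genes are reported as a list. Each cluster is described by its top 5 genes. Shares at 1 depth used cells thinned to 1500 UMIs and exact paired permutation tests. In thinned cells every gate was read from the thinned counts. The gates, tests, lists, naming rules and most alternative settings were chosen before the data were examined.

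The alternative settings chosen then were DESeq2 size factors, the DESeq2 Wald test, no low-count filter, no library block, each library left out, no matching, another draw (seed 2), called doublets kept, cells with a UMI of another cell type left out (5 of the marker genes were in the table), a gate of at least 2 UMIs, thinned cells, Leiden resolutions 0.4 and 1.6, no centring, a stricter cell filter (800 genes, 5% mitochondrial) and none, and thinning to 750 UMIs. Chosen after seeing the data were the analysis of shared barcodes, alternatives without shallow copies and without 3 clusters of low UMI counts (1, 4 and 5, not cluster 6, which is low but mostly shallow copies), the list tests without cells that show a UMI of another cell type, 20 further draws per gate, 20 control genes per gate (detection within 20% of the gate gene's, drawn at random outside the lists), 20 further draws of those of HLA-DRA, and the IL2RA and TRDC gates. Where a barcode sequence occurred in several libraries, the deepest was called the original. Each copy was compared with all originals and unshared barcodes of the original's library by the likelihood of its counts, with profiles smoothed by 200 UMIs.

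Gene positions are from GENCODE release 29 (GRCh38), in which 12990 of the table's symbols were found; the authors' build may differ. LINC00152 and MIR4435-2HG, MZT2A and its near copy MZT2B, and EEF1B2 and its pseudogenes are nearly identical in sequence, so their reads are not separable with certainty. Tools were Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.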

Results

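T cells carrying CD4 and CD25 were sorted from the blood of 3 healthy donors and profiled by droplet single-cell RNA sequencing of transcript 3′ ends. CD25, the alpha chain of the interleukin-2 receptor, is carried by regulatory T cells (Treg) and by activated conventional T cells. All 3 samples belonged to 1 group. The comparisons were made between cells within libraries, with the library as the replicate (n = 3). The count table held 15362 genes and 2973 cell barcodes in 3 libraries, numbered 1 to 3 here by their barcode suffix, which no label tied to a donor. Libraries 1, 2 and 3 held 930, 665 and 1378 barcodes with 2520280, 1660810 and 4511264 UMIs (unique molecular identifiers, each standing for a captured transcript). After filtering, 698, 432 and 1116 cells remained, with 2335815, 1423964 and 4219390 UMIs. The median cell had 3172 ± 584 UMIs and 1108 ± 60.5 detected genes, and 2.56 ± 0.224% of its UMIs were mitochondrial (mean of the library medians ± SD, n = 3).

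The 2246 cells fell into 7 clusters, of which 4 were named after a cell class. Cluster 0 (591 cells) had the markers of Treg. FOXP3, the transcription factor that defines the lineage, stood at 118 ± 20.2 CPM (1 CPM is 0.0001% of the UMIs of the summed cells; mean ± SD, n = 3 libraries), and IL2RA, which encodes CD25, at 179 ± 17.2 CPM. Its top 5 genes were LINC00152, MIR4435-2HG, LGALS3, HLA-DPB1 and CCR10. It had as many raised markers of effector memory cells (5 of 7) as of Treg (5 of 7). Cluster 3 (349 cells) was named cytotoxic T-like for 3 of 7 raised markers (CCL5, GZMA and GZMK). CCL5, a chemokine of cytotoxic lymphocytes, stood there at 131 ± 46.9 CPM against 19.0 ± 6.07 CPM in cluster 0. KLRB1, which encodes CD161, stood at 781 ± 94.97 CPM. Its top 5 genes were KLRB1, CCL5, ANXA1, ID2 and TRDC, the last being the constant gene of the T cell receptor delta chain. In cluster 2 (605 cells, unnamed), CCR7, a receptor for lymph node entry, stood at 126 ± 42.2 CPM against 44.7 ± 16.8 CPM in cluster 0. Its next genes were AIF1, ACTN1, TXK and PLAC8. Cluster 6 (46 cells), named cycling-like, raised 7 of 7 cycling markers and was led by MKI67, HIST1H4C, TYMS, STMN1 and RRM2.

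Of the cells of a library, 35.4 ± 4.22% were Treg-like (clusters 0 and 1), 15.4 ± 3.72% cytotoxic T-like, 2.01 ± 0.267% cycling-like and 47.2 ± 3.13% unnamed (mean ± SD, n = 3). Clusters 1, 4 and 5 held cells of low depth, with medians of 1219.5, 1853 and 951 UMIs against 4382 in cluster 0. The median of the cycling-like cluster 6, described below, was also low (1559.5 UMIs). Cluster 1 (180 cells, 8.65 ± 3.21%) was led by MTRNR2L1, MIAT, TTN, GPR155 and FAS, and its median mitochondrial share was 6.51%. It was named for 5 of 7 raised Treg markers (IL2RA, CTLA4, IKZF2, TIGIT and RTKN2), none among its top 10 genes. FOXP3 was not among the 5. It stood at 92.4 ± 50.3 CPM in cluster 1 and had a UMI in 11.3 ± 4.25% of its cells. Cluster 4 (458 cells, 20.5 ± 1.90%) was led by C1orf56, CTC-425F1.4, PHKG1, MTA2 and CDC42SE1. Cluster 5 (17 cells, 0.953 ± 0.672%) was led by CENPT, PREB, ISYNA1, TMEM175 and SNHG25. It raised 4 of 7 Treg markers (FOXP3, IL2RA, CTLA4 and TNFRSF4) and 3 of 7 of effector memory cells. It stayed unnamed by the rule on depth. No cluster carried 3 markers of B cells, monocytes, NK cells or dendritic cells. The table held 1 marker of CD8 T cells, 1 of red cells and 0 of platelets. The rule of 3 markers could thus not name these 3 classes, and their absence was not tested by it. LYZ, CD79A and HBB had a UMI in 1.04 ± 0.219%, 2.45 ± 0.719% and 0.811 ± 0.313% of cells. The names depended on the clustering. At doubled resolution the Treg-like share was 19.8% and a B-like class of 1.97 ± 0.509% appeared. At halved resolution the cells were named effector memory-like (49.4 ± 4.01%) or naive/central memory-like (48.6 ± 3.81%), apart from the cycling-like cells. No cytotoxic class was named without centring, with called doublets kept, or after reclustering without the shallow copies described next, which left no cycling-like class either.

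**Figure D1:**
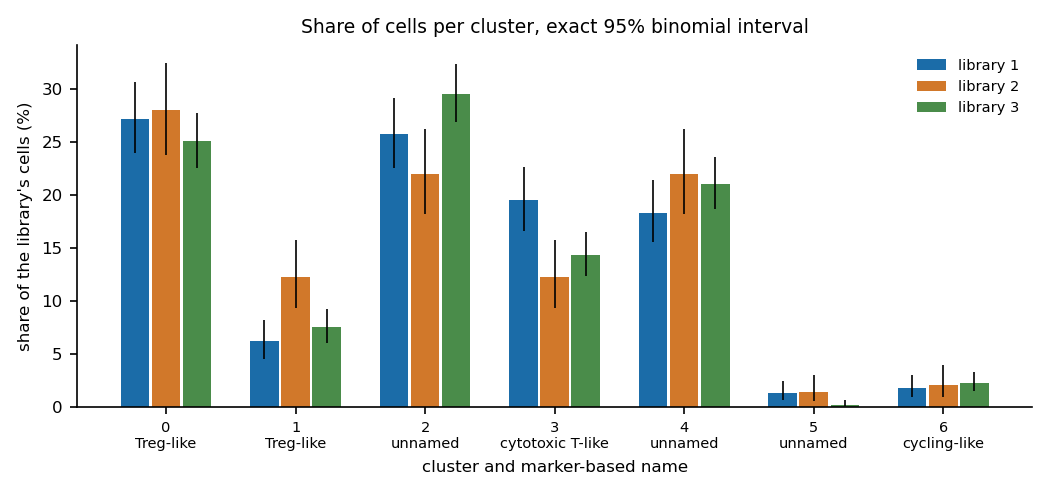
Share of each library's cells (%, vertical axis) in the 7 clusters (horizontal axis), with bars for libraries 1 to 3 and exact 95% binomial intervals. Clusters 0 and 2 were the largest, at 26.8 ± 1.51% and 25.8 ± 3.79% (mean ± SD, n = 3).

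The same barcode sequence occurred in more than 1 library for 276 barcodes, 126 of them in 2 libraries and 150 in 3. The deepest of the barcodes that shared a sequence is called the original here and the others its shallow copies. The 426 copies made up 14.3% of all barcodes and 3.57% of all UMIs. A copy had 0.112 times the UMIs of its original (median; quartiles 0.0861 and 0.131), and the copies had a median of 645.5 UMIs against 5746.5 in the originals. None of 1272 originals and unshared barcodes below the median depth of their library was shared (0 of 1272, which allows a share of up to 0.236%), against 276 of 1275 (21.6%) at or above it. Most copies fell to the filter on genes per cell, which left 35. Of the 46 cycling-like cells, 34 were copies (73.9%, exact 95% binomial interval 58.9 to 85.7%). They had a median of 1231.5 UMIs against 15324 in the other 12 cells. Without the copies the cycling-like share was 0.639 ± 0.466% (n = 3), and when the cells were clustered anew without them no cluster was named cycling-like.

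**Figure D2:**
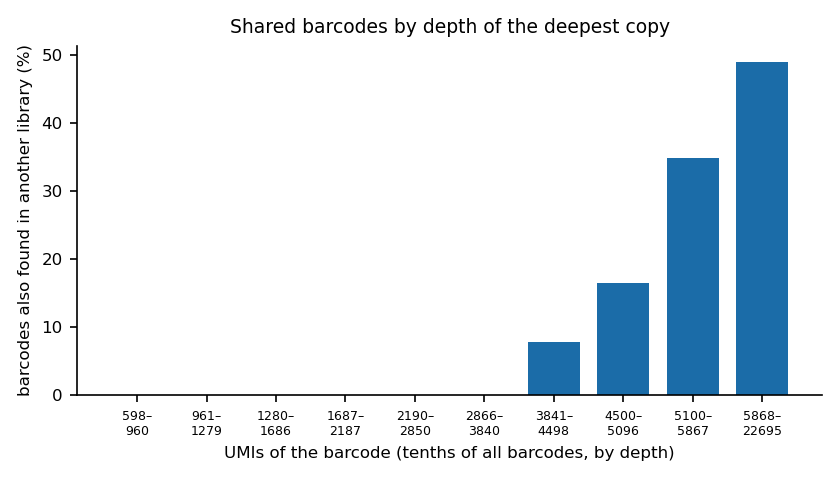
Percentage of barcodes also found in another library (vertical axis) by depth in UMIs (horizontal axis, barcodes other than copies in 10 classes of about equal size). Sharing was 7.84%, 16.5%, 34.9% and 49.0% in the 4 deepest classes and 0% in the others.

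Cells with a FOXP3 UMI were compared with cells without one, to ask which transcripts go with FOXP3 in a sort that takes in both Treg and activated conventional T cells. IL7R, the interleukin-7 receptor chain that is low on Treg, was lower in FOXP3-positive cells (log2 fold change -0.59, SE 0.10, adjusted p = 4.22e-05, lower in 3 of 3 libraries). ANXA1 (-0.49, SE 0.12, adjusted p = 0.0161) and KLRB1 (-0.45, SE 0.10, adjusted p = 0.00891), both among the top genes of the cytotoxic T-like cluster, were lower too. So were CERS5 (-1.10, SE 0.29), C1orf162 (-0.78, SE 0.20), CAMK4 (-0.57, SE 0.14) and 3 ribosomal protein genes. HMGB2 and STMN1, chromatin and tubulin-binding proteins abundant in dividing cells, rose by 0.50 (SE 0.11, adjusted p = 0.00261) and 0.57 (SE 0.15), STMN1 without the same sign in every library. The glycolytic enzyme gene GAPDH rose by 0.36 (SE 0.07, adjusted p = 0.00208) and the galectin gene LGALS1 by 0.42 (SE 0.10). Genes of antigen presentation by major histocompatibility complex (MHC) class II rose as well, HLA-DRA by 0.68 (SE 0.17, adjusted p = 0.0161) and HLA-DPB1 by 0.59 (SE 0.13, adjusted p = 0.00465). CD74, the invariant chain, rose by 0.39 (SE 0.09) without the same sign in every library. The other rises were CYB5R4 (1.11, SE 0.29), VAMP5 (0.59, SE 0.14), LINC00152 (0.54, SE 0.13) and SLC25A5 (0.51, SE 0.12).

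In all, 11 genes rose and 9 fell with FOXP3 of 5115 tested by edgeR (424 at an unadjusted p under 0.05), 18 of them with the same sign in 3 libraries. The classes held 136, 111 and 243 cells each in libraries 1 to 3, and 409930 to 1054500 UMIs per sum. FOXP3 (X, 49250436 to 49264826 of GRCh38, minus strand) had a UMI in 22.5 ± 3.39% of cells. The sort holds no cell type sure to lack FOXP3. Its share was 37.4 ± 4.22% in cluster 0 (median 4382 UMIs) and 18.9 ± 3.64% in the cytotoxic T-like cluster 3 (median 4442 UMIs). The calls were unstable. Without library 1, 12 genes rose and 1 fell, and without library 2, 0 rose (182 at an unadjusted p under 0.05) and 4 fell. Further, 3 rose and 2 fell without library 3. In 20 further random draws of the compared cells 0 to 20 genes rose and 0 to 89 fell. IL7R passed in 18 draws, HMGB2, GAPDH and ANXA1 in 15, HLA-DPB1 in 3, and HLA-DRA, CD74 and CYB5R4 in 0. STMN1 passed in 10, LGALS1 in 9, C1orf162 in 8, LINC00152 in 7, KLRB1 and SLC25A5 in 5, VAMP5 in 3, and CERS5 and CAMK4 in 1. HLA-DRA stood at -0.23 with every cell thinned to 1 depth. Used as gates in the same way, with 1 draw each, 20 control genes detected in about as many cells gave 0 to 87 calls. Of them 6 gave at least the 20 calls of FOXP3, and 4 at least the median of its further draws (45.5).

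Of the gene lists fixed before the data were examined, the 12 tested Treg core genes were higher with FOXP3 by camera (median log2 fold change 0.24, 10 of 12 positive, adjusted p = 0.00944, adjusted p = 0.512 with an estimated correlation). None of the 12 passed alone by edgeR or when adjusted over the list alone. The smallest p values were those of the checkpoint receptor TIGIT (0.42, SE 0.15), ENTPD1 (0.78, SE 0.35), IL2RA (0.30, SE 0.14) and CTLA4 (0.25, SE 0.20). The 7 conventional T cell genes were lower (median -0.35, adjusted p = 0.00944, adjusted p = 0.512 with an estimated correlation). IL7R alone passed over all genes, and 1 gene adjusted over the list alone. The 5 MHC class II genes were higher (median 0.59, adjusted p = 0.000159, adjusted p = 0.512 with an estimated correlation). Of them 3 passed over all genes and 4 adjusted over the list alone. In 20 further draws their median was lower (0.08 to 0.58, median 0.26), and the list passed in 14. Also higher were the 5 cell cycle genes (median 0.50, adjusted p = 0.00944, adjusted p = 0.512 with an estimated correlation), where 2 passed and 4 did when adjusted over the list alone. Ribosomal protein genes (86 tested, median -0.17, adjusted p = 5.86e-08) and mitochondrial genes (13 tested, median -0.17, adjusted p = 0.00944) were lower, each with adjusted p = 0.512 with an estimated correlation. By edgeR, 3 and 0 passed over all genes, and 61 and 7 adjusted over the list alone. With the 20 control genes as gates, the ribosomal median ran from -0.216 to 0.012 and the mitochondrial median from -0.194 to 0.036. For each list 1 control gene was at or below FOXP3, and 0 of 20 further FOXP3 draws fell below all control genes. Without library 2, the lists past the threshold went from 6 to 2, as Treg core (adjusted p = 0.185), conventional T (0.0655), cell cycle (0.205) and mitochondrial genes (0.108) no longer passed. Without library 1, conventional T (0.216) and mitochondrial genes (0.120) did not pass. In thinned cells, with FOXP3 read after thinning, the MHC class II median was -0.062 (camera adjusted p = 0.845). Treg core (median 0.245) and cell cycle genes (0.147) did not pass there (camera adjusted p = 0.845 each). Nor did mitochondrial genes (-0.183, camera adjusted p = 0.268), while ribosomal protein genes were lower (-0.202, camera adjusted p = 9.1e-05).

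The other lists did not pass in the FOXP3 gate: naive and central memory (adjusted p = 0.137, lower), effector memory (0.221, higher), homing receptors (0.590), cytotoxic and Th1 (0.801), Th2 and Th17 (0.180, lower), interferon response (0.137, higher), immediate early and stress (0.184, lower) and glycolysis (0.320, higher). Without library 3, cytotoxic and Th1 genes passed (0.000902, higher). For homing receptors the test pointed up with a median of -0.06 and a mean of 0.03. For cytotoxic and Th1 genes it pointed up with a median of -0.04 and a mean of -0.03. Adjusted over the list alone, 1 gene of the naive and central memory list, TCF7 (-0.42, SE 0.14), and 2 of the effector memory list, LGALS1 up and S100A11 down (-0.29, SE 0.10), passed. In the Th2 and Th17 list KLRB1, RORA (-0.27, SE 0.12) and GATA3 (0.37, SE 0.16) did. Of the markers of other cell types, CD79B of B cells (0.14, SE 0.23, adjusted p = 0.94995) and AIF1 of monocytes (-0.46, SE 0.28, adjusted p = 0.719) were the 2 with enough counts to test. No NK, CD8 T, dendritic cell, platelet or red cell marker had enough.

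Among FOXP3-positive cells, those with an HLA-DRA UMI were compared with those without, since HLA-DR marks a subset of human Treg. HLA-DRA (chromosome 6, 32439842 to 32445046, plus strand) had a UMI in 32.4 ± 12.8% of cluster 0 and 14.5 ± 6.18% of cluster 3, at medians of 4382 and 4442 UMIs. All 4 of the other MHC class II genes tested rose, HLA-DMA by 1.87 (SE 0.39), HLA-DPB1 by 1.61 (SE 0.22), HLA-DPA1 by 1.44 (SE 0.25) and CD74 by 1.32 (SE 0.16, adjusted p = 8.34e-08) in log2 units. As a list they were higher (median 1.52, camera adjusted p = 1.54e-08, adjusted p = 0.266 with an estimated correlation), and 4 passed when adjusted over the list alone. CCR10, a receptor for skin homing, rose by 2.77 (SE 0.69, adjusted p = 0.00569), from 12.9 ± 5.80 to 92.1 ± 25.7 CPM (41 UMIs against 5). LINC00152 (0.87, SE 0.21), SAT1 (0.85, SE 0.19), CALM3 (0.81, SE 0.20), MZT2A (0.81, SE 0.20), LGALS1 (0.76, SE 0.18), S100A4 (0.32, SE 0.08) and GAPDH (0.53, SE 0.11) rose as well.

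TCF7, a transcription factor of naive and memory T cells, was lower in the HLA-DRA-positive cells (log2 fold change -1.23, SE 0.31, adjusted p = 0.00539). So were IFITM1 (-1.10, SE 0.18), the chaperone gene HSPE1 (-1.05, SE 0.28), KLRB1 (-1.02, SE 0.19, adjusted p = 0.000148), MYC (-1.002, SE 0.31), IL7R (-0.999, SE 0.22, adjusted p = 0.00102), APRT (-0.88, SE 0.18), SRRM2 (-0.81, SE 0.23), TIPIN (-0.73, SE 0.18) and the translation factor gene EEF1B2 (-0.57, SE 0.12). Ribosomal protein genes made up 68 of the 101 falls (81 tested, median -0.37, adjusted p = 1.86e-19, adjusted p = 0.338 with an estimated correlation). Of them 73 fell and 1 rose when adjusted over the list alone. Of 12 mitochondrial genes, 9 fell, and 10 when adjusted over the list alone (median -0.34, adjusted p = 5.52e-05, adjusted p = 0.266 with an estimated correlation). MT-ND3 stood at -0.57 (SE 0.08) and MT-ND2 at -0.46 (SE 0.08). In thinned cells the mitochondrial median had the opposite sign (0.077, 11 tested, camera adjusted p = 0.483). The ribosomal median there was -0.389 (75 tested, camera adjusted p = 2.86e-12). In all, 25 genes rose and 101 fell of 2024 tested by edgeR (273 at an unadjusted p under 0.05), all with the same sign in 3 libraries. The classes held 40, 28 and 37 cells each and 108420 to 169860 UMIs per sum. Without libraries 1, 2 and 3 in turn, 15, 13 and 7 rose and 63, 80 and 29 fell. In 20 further draws 6 to 31 genes rose and 3 to 103 fell. HLA-DMA, HLA-DPB1, HLA-DPA1, CD74, LGALS1, IFITM1 and EEF1B2 passed in all 20, TCF7 and APRT in 19, LINC00152 in 18, SAT1 in 17 and IL7R in 16. TIPIN passed in 13, HSPE1 in 12, MZT2A in 9, CALM3 and MYC in 3 and SRRM2 in 2. KLRB1 passed in 12 and ran from -1.20 to 0.20. CCR10 had enough counts in 14 draws and passed in 13. None of 20 control genes, with 1 draw each, called as many (0 to 96), and 13 of the 20 further draws called more than 96. Drawn 20 times as well, the control gene with most calls had a median of 55 (9 to 112) against 113 for HLA-DRA.

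Another 3 lists passed in the HLA-DRA gate. Effector memory genes were higher (16 tested, median 0.24, adjusted p = 0.0379, adjusted p = 0.338 with an estimated correlation). LGALS1, S100A4 and IL32 (0.25, SE 0.08) rose over all genes and 6 when adjusted over the list alone. This list did not pass without library 1 (adjusted p = 0.276). Naive and central memory genes were lower (8 tested, median -0.36, adjusted p = 0.00288, adjusted p = 0.346 with an estimated correlation), though TCF7 was the 1 gene past the threshold in either adjustment, and the list did not pass without library 3 (adjusted p = 0.142). Immediate early and stress genes were lower (8 tested, median -0.18, adjusted p = 0.0434, adjusted p = 0.338 with an estimated correlation) with 0 passing alone by edgeR, and 0 when adjusted over the list alone. They did not pass without library 1 (adjusted p = 0.286) or library 2 (adjusted p = 0.208). Effector memory genes passed in 20 of 20 further draws, naive and central memory genes in 12 and immediate early and stress genes in 6. Treg core genes (8 tested, median 0.03, adjusted p = 0.702), homing receptors (0.749), Th2 and Th17 (0.120), interferon response (0.404), cell cycle (0.341) and glycolysis (0.0638) did not pass. Glycolysis passed without library 3 (0.0219, higher), and cell cycle without library 1 (0.01785, higher) and library 2 (0.0245, lower). The test pointed up for homing receptors (median -0.10, mean 0.21) and for cell cycle genes (median -0.05, mean 0.04). Of the conventional T list only IL7R had enough counts, and of the cytotoxic and Th1 list no gene. Of the markers of other cell types only CD79B did (0.86, SE 0.55, adjusted p = 0.588).

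The effect of HLA-DRA was then compared between FOXP3-positive and FOXP3-zero cells, to ask whether the genes that go with HLA-DRA differ between them. FAM107B was lower with HLA-DRA in FOXP3-positive cells (-0.65) and higher in FOXP3-zero cells (0.63), a difference of -1.35 (SE 0.31, adjusted p = 0.0390) with opposite signs in 3 of 3 libraries. MT-ND3, a subunit of respiratory complex I, was lower in FOXP3-positive cells (-0.58) against -0.04 in FOXP3-zero cells, a difference of -0.53 (SE 0.13, adjusted p = 0.0390). These 2 were the only genes called of 2493 tested. By count 0 were higher and 2 lower by edgeR (121 at an unadjusted p under 0.05), and 0 and 1 by DESeq2, whose 1 call was neither of these genes. The 12 mitochondrial genes were lower as a list (median -0.35, adjusted p = 0.000129, adjusted p = 0.311 with an estimated correlation). In it 1 gene passed over all genes and 9 when adjusted over the list alone. The MHC class II genes did not differ past the threshold (4 tested, median 0.06, adjusted p = 0.613), nor did CCR10 alone (2.20, SE 0.74, adjusted p = 0.558).

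With another random draw of the compared cells FAM107B stood at -0.75 and MT-ND3 at -0.20, and neither was called. Nor was either called with no matching, no low-count filter or doublets kept, or without shallow copies, low-depth clusters or cells that show a UMI of another cell type. Neither gene was called without library 2 or without library 3 (0 up and 0 down by edgeR, with 75 and 82, and 54 and 52, at an unadjusted p under 0.05). Without library 1 there were 1 rise and 2 falls, and MT-ND3 was not among them (adjusted p = 0.0837). The mitochondrial list did not pass without library 2, when 0 lists did. The other lists did not pass: ribosomal proteins (adjusted p = 0.0686), naive and central memory (0.259), glycolysis (0.259), immediate early and stress (0.424), cell cycle (0.509), effector memory (0.585), Treg core (0.613), Th2 and Th17 (0.702), interferon response (0.853) and homing receptors (0.860). For Treg core genes the test pointed down with a median of 0.05 and a mean of -0.15. For homing receptors (median -0.24, mean 0.03) and interferon genes (median -0.15, mean 0.09) it pointed down too. Adjusted over the list alone, CCR10 and the effector memory gene CRIP1 (-0.60, SE 0.20) also passed.

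Among FOXP3-positive cells, those with a CCR7 UMI were compared with those without, CCR7 being carried by naive and central memory cells. CCR7 (chromosome 17, 40553769 to 40565472, minus strand) had a UMI in 31.4 ± 13.6% of cluster 2 and 15.9 ± 4.29% of cluster 0, at medians of 4087 and 4382 UMIs. Effector memory genes were lower with CCR7, S100A4 by a log2 fold change of -0.48 (SE 0.06, adjusted p = 6.86e-09), the cytokine gene IL32 by -0.40 (SE 0.07, adjusted p = 1.28e-05) and ANXA2 by -0.77 (SE 0.20, adjusted p = 0.00853). ANXA11 (-0.85, SE 0.24) and FTH1, the ferritin heavy chain (-0.26, SE 0.07), fell as well. PLAC8, also a top gene of the CCR7-high cluster 2, rose by 1.25 (SE 0.28, adjusted p = 0.00188). The next rises were HSD17B11 (0.95, SE 0.28), the DNA damage kinase gene ATM (0.86, SE 0.27), the T cell surface gene CD7 (0.84, SE 0.22) and EEF1B2 (0.41, SE 0.10). Of the 54 rises, 37 were ribosomal protein genes and 7 mitochondrial. These included MT-ND3 (0.36, SE 0.07), MT-ATP6 (0.29, SE 0.07), MT-ND2 (0.29, SE 0.07), MT-CO3 (0.25, SE 0.06) and MT-ND4 (0.25, SE 0.07).

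In all, 54 genes rose and 5 fell with CCR7 of 1594 tested by edgeR (179 at an unadjusted p under 0.05), 58 of them with the same sign in 3 libraries. The classes held 32, 21 and 71 cells each and 105450 to 301660 UMIs per sum. Without library 1, 0 rose and 0 fell (103 and 57 at an unadjusted p under 0.05). Without library 3, 1 rose and 1 fell, and without library 2, 46 rose and 7 fell. Without the shallow copies 11 rose and 3 fell, and 20 further draws gave 0 to 63 rises and 0 to 10 falls. In these draws IL32 passed in 16, S100A4 and MT-CO3 in 15, PLAC8 in 13, and ANXA2, CD7 and MT-ND3 in 12. MT-ATP6 passed in 11, EEF1B2 in 9, MT-ND2 and MT-ND4 in 8, ANXA11 in 6, ATM in 3 and FTH1 in 1. HSD17B11 passed in 0, with log2 fold changes of 0.37 to 0.71. The 20 control genes, with 1 draw each, gave 0 to 20 calls, and 9 of the 20 further draws called more than 20. With a gate of at least 2 UMIs, which left 439 genes to test, 0 rose and 0 fell (7 and 23 unadjusted). MT-ND3, MT-ATP6, MT-ND2 and MT-ND4 had the opposite sign there (-0.26, -0.036, -0.30 and -0.021). With every cell thinned to 1 depth, EEF1B2 and MT-ATP6 did (-0.25 and -0.049).

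As lists, effector memory genes were lower with CCR7 (15 tested, all negative, median -0.31, adjusted p = 8.49e-07, adjusted p = 0.528 with an estimated correlation). Of them 3 fell over all genes and 8 adjusted over the list alone. MHC class II genes were lower (4 tested, median -0.45, adjusted p = 0.0180, adjusted p = 0.554 with an estimated correlation). By edgeR 0 of them passed over all genes and 3 adjusted over the list alone, among them CD74 (-0.40, SE 0.15). The list did not pass without library 1 (adjusted p = 0.341) or library 3 (adjusted p = 0.255), and passed in 10 of 20 further draws. Ribosomal protein genes (78 tested, median 0.18, adjusted p = 7.98e-09) and mitochondrial genes (12 tested, median 0.25, adjusted p = 0.000339) were higher, each with adjusted p = 0.554 with an estimated correlation. In these, 58 and 9 passed when adjusted over the list alone. With at least 2 UMIs as the gate neither list passed by camera (medians 0.01 and -0.05, adjusted p = 0.931 and 0.325). In thinned cells the ribosomal median had the opposite sign (-0.035, camera adjusted p = 0.0320). The mitochondrial median there was 0.25 (camera adjusted p = 0.0129). The naive and central memory genes did not pass, though all 6 tested were positive (median 0.06, adjusted p = 0.655), TCF7 at 0.41 (SE 0.27) and LEF1 at 0.34 (SE 0.24). Treg core (adjusted p = 0.204, lower), Th2 and Th17 (0.946), interferon response (0.453), cell cycle (0.533), immediate early and stress (0.946) and glycolysis (0.345) did not pass either. Treg core genes passed without library 2 (0.0163, lower) and cell cycle genes without library 3 (0.0494, higher). The test pointed down for Th2 and Th17 genes (median 0.09, mean -0.02) and up for immediate early genes (median -0.10, mean -0.09). Of the conventional T list only IL7R was tested (0.68, SE 0.22, adjusted p = 0.0704, past the threshold when adjusted over the list alone). Of the homing receptors only CXCR4 (-0.40, SE 0.18) and SELPLG (-0.31, SE 0.23) were tested, and no marker of another cell type was.

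**Figure D3:**
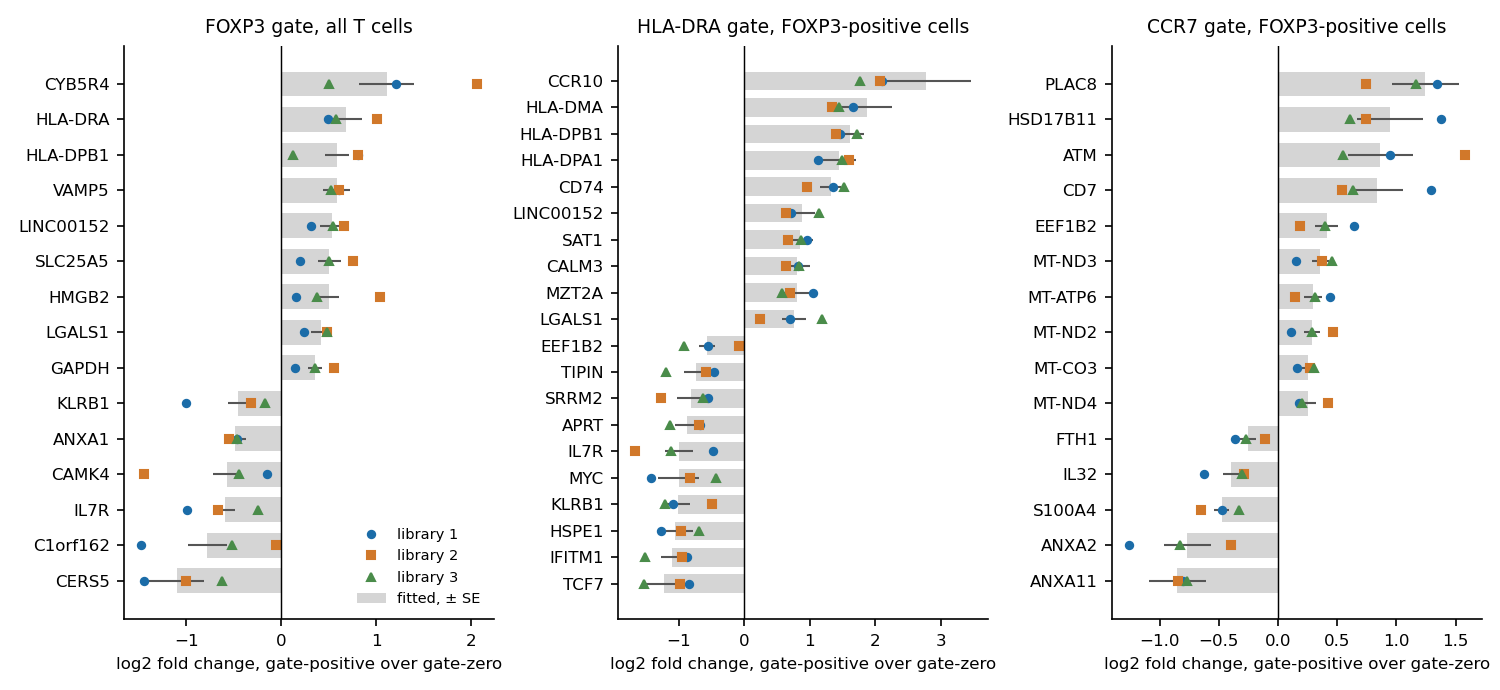
Log2 fold change (horizontal axes) of the genes named by the rule in each gate, gate-positive over gate-zero cells, as the fitted value ± SE (grey bars and lines) and per library (points; n = 3). Each gene shown had the same sign in 3 of 3 libraries.

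**Figure D4:**
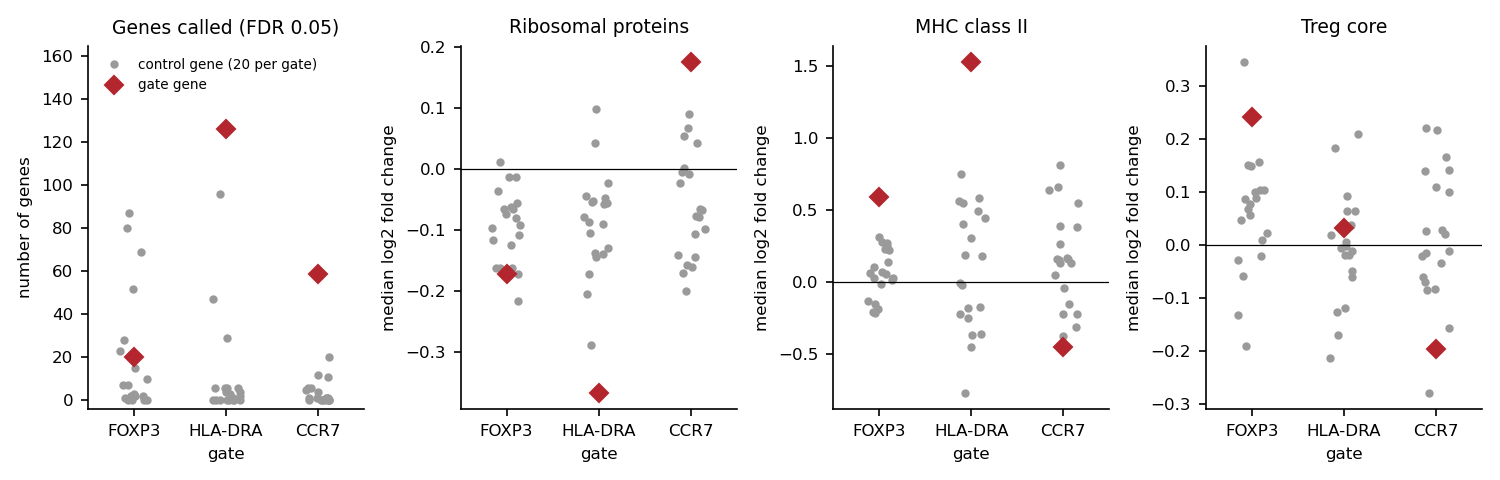
Number of genes called and median log2 fold change of 3 gene lists (vertical axes) for the 3 gate genes (diamonds) and for 20 control genes used as gates in place of each (dots). In the draw shown, HLA-DRA (126 calls) and CCR7 (59) lay above all of their control genes and FOXP3 (20) did not. In 20 further draws HLA-DRA did in 13, CCR7 in 9 and FOXP3 in 1.

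The share of cells with an HLA-DRA or a CCR7 UMI was compared between FOXP3-positive and FOXP3-zero cells at 1 depth, with every cell thinned to 1500 UMIs. HLA-DRA was detected in 11.3 ± 5.56% of FOXP3-positive and 10.7 ± 5.36% of FOXP3-zero cells (mean ± SD, n = 3), a difference of 0.591 ± 0.773 percentage points (exact paired permutation test, two-sided p = 0.5). CCR7 was detected in 10.0 ± 3.59% and 10.1 ± 5.87%, a difference of -0.126 ± 5.07 points (exact paired permutation test, two-sided p = 1.0). The HLA-DRA difference was 0.350, 1.04 and 0.386 points without libraries 1, 2 and 3 in turn, and -0.199 without shallow copies. The CCR7 difference was -1.13 without library 1, -2.01 without library 2 and 2.76 without library 3. Without thinning the shares were 25.3 ± 8.85% against 16.0 ± 6.25% for HLA-DRA and 26.2 ± 7.22% against 19.7 ± 9.68% for CCR7 (exact paired permutation test, p = 0.25 each). Thinning left out 380 cells, and with 3 libraries the smallest p this test allows is 0.25, so it could not detect a difference at any depth.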

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

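Chosen only after the result was seen were the tests of chance sharing of barcodes, of copies in the cycling-like cluster, of B cell or monocyte RNA, of the low-depth clusters, of the further draws of HLA-DRA and its control genes and of other splits of the sums. The tests of the copies' nearest match, of the control genes and of at least 2 FOXP3 UMIs were chosen after the pattern but before their own values were seen. The labels give 1 group, so no biological explanation was tested for the patterns below.

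Barcodes found in more than 1 library left 426 shallow copies. The comparisons do not use which barcodes were shared, though 35 copies stayed among the cells after filtering, and 34 of the 46 cycling-like cells were copies (73.9%). Chance sharing is argued against by 2 values. Among originals and unshared barcodes, 0 of 1272 below the median depth of their library were shared (a share of up to 0.236%) against 21.6% at or above it. Taking the deepest as the original favours such a gap, but chance would still leave some originals below the median. A copy made by chance would also not match its own original best. Molecules counted in the wrong library may be the source, since the copy's own original was its nearest match for 426 of 426 copies (100%), among 537 to 1239 candidates. This test does not separate a swapped sample index from molecules mixed between libraries before sequencing. The cycling-like cluster may thus hold 12 cells of its own and copies of 23 deep barcodes, whose originals lay in cluster 0 (12), cluster 6 (8) and cluster 3 (1) or were called doublets (2).

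With HLA-DRA in FOXP3-positive cells, MHC class II genes were higher (median log2 fold change 1.52) and ribosomal protein genes lower (-0.37). Low-depth cells in clusters 1, 4 and 5 are argued against as the whole cause of the ribosomal fall, since the median was -0.32 without them. A fall in any gate of like detection is argued against as the whole cause too. The lowest median over 20 control genes was -0.289 with 1 draw each. Over 20 further draws the lowest control gene had a median of -0.240 (SD 0.042) against -0.334 (SD 0.029) for HLA-DRA. Its lowest draw (-0.317) overlapped the draws of HLA-DRA (-0.386 to -0.28902), so such a gate may account for part of the fall. RNA of B cells or monocytes stays open. Without cells that had a UMI of CD79A, MS4A1, LYZ or other marker genes the MHC class II median was 1.498. This filter took only 6 of 105 matched positive cells (5.71%), as the 3 genes were seen in 2.45%, 1.47% and 1.04% of cells, and RNA spread over other cells would pass it. The sort on CD4 and CD25 should remove most such cells, but not their free RNA. The purity of the sort was not tested here. At doubled resolution 42 cells (1.97%) were named B-like. The main clustering named no B-like cluster, so these cells were not left out of the gates as a class. A state of the cells themselves was not tested.

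The number of genes called in the FOXP3 gate, 20 here, ran from 1 to 97 over 20 further draws (median 45.5), with IL7R past the threshold in 18 and HLA-DRA in 0. A gate on some genes of like detection may do as much. Of 20 control genes, with 1 draw each, 6 called at least 20 genes and 14 fewer, and 4 reached the median of 45.5. The MHC class II median of FOXP3 was 0.59 against at most 0.31 for a control gene, but in 20 further draws it ran from 0.08 to 0.58 and exceeded that in 7. With every cell thinned to 1 depth this median was -0.062. Cells that express FOXP3 without a UMI, or free FOXP3 RNA, could mix the classes. The Treg core median was larger with at least 2 UMIs than with at least 1 in 2 of 3 libraries (0.20, 0.44 and 0.57 with at least 2 against 0.29, 0.27 and 0.17 with at least 1 in libraries 1 to 3, 6 genes). The test leaves this open.

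The effect of HLA-DRA differed between FOXP3-positive and FOXP3-zero cells, by the test of the difference, for FAM107B (log2 difference -1.35), for MT-ND3 (-0.53) and for the mitochondrial list (adjusted p = 0.000129, adjusted p = 0.311 with an estimated correlation). MT-ND3 did not pass without library 1 (adjusted p = 0.0837). Neither gene passed without library 2 or without library 3, nor by the DESeq2 Wald test, with another draw (-0.75 and -0.20), no matching (-0.64 and -0.40), no low-count filter (-1.33 and -0.52) or doublets kept (-0.94 and -0.47). The same held without shallow copies (-1.10 and -0.38), without cells that show a UMI of another cell type (-0.81 and -0.23) and without the low-depth clusters (-0.74 and -0.26). The list did not pass without library 2 (adjusted p = 0.0797) or without the low-depth clusters (adjusted p = 0.114).

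The 6 sums of each gate can be split in 10 ways, too few for a share under 0.05. The 1 real split called 20, 126 and 59 genes in the FOXP3, HLA-DRA and CCR7 gates, and the highest of the others 3, 1 and 1. Among the other splits that part the classes in all 3 libraries the highest were 1, 0 and 1 by edgeR, and the remaining splits part them in 1 library. For the interaction, exchanges of the FOXP3 label between the pairs were fitted with each pair as a block, which called 4 genes for the real labels in place of 2, and 1 at most for the others.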

How the results depend on the processing

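The alternatives without shallow copies or without the 3 clusters of low UMI counts, the reclustering, the list tests without cells that show a UMI of another cell type, and the 20 further draws were tests chosen only after the results were seen. The others were planned. Apart from leaving out a library, main values and counts stayed the same 82 times and moved 75 times. Results of named genes were the same 301 times, weaker 281 times and reversed 7 times. Single lists were the same 256 times, weaker 26, stronger 11 and reversed 1 time. With a library left out, named genes were the same 58 times and weaker 98 times (40 of 52 without library 3), and single lists the same 128 times, weaker 13, stronger 5 and reversed 1 time. DESeq2 size factors left 52 of 52 named-gene results past the threshold, the DESeq2 Wald test 3 and no library block 2. Depth was a limit where cells were thinned to 1 depth, which left 365 genes to test in the HLA-DRA gate against 2024. Alternatives that change the cells also change the matched draw, and further draws alone gave 0 to 20 rises and 0 to 89 falls for FOXP3, 6 to 31 and 3 to 103 for HLA-DRA, and 0 to 63 and 0 to 10 for CCR7. Where an alternative's count lies within these ranges, its effect is not separable from that of the draw. No matching and thinned cells use no matched draw. In the HLA-DRA gate the rises with no matching and with at least 2 UMIs, given below, lay above the range. Beyond this the cause was not tested.

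In the FOXP3 gate (11 up, 9 down by edgeR) there were 1 up and 45 down with the DESeq2 Wald test, which gave an adjusted p for 256 genes, and 14 down with no low-count filter. Another draw gave 6 up, called doublets kept 7 up and 47 down, cells with a UMI of another cell type left out 7 up and 51 down, and a gate of at least 2 UMIs 21 up and 79 down. Thinned cells gave 0 up (49 at an unadjusted p under 0.05) and 5 down. There were 55 down without shallow copies (7 of them shared with the main result) and 7 up and 71 down without the low-depth clusters. Leaving out a library gave 0 to 12 up and 1 to 4 down, the 0 without library 2 (182 unadjusted). HLA-DRA turned to -0.23 in thinned cells.

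In the HLA-DRA gate (25 up, 101 down) there were 7 up with the DESeq2 Wald test, 15 up and 55 down with no low-count filter, 52 up with no matching, 59 up with at least 2 UMIs and 14 up without the low-depth clusters. Thinned cells gave 2 up and 0 down (24 unadjusted). Leaving out a library gave 7 to 15 up and 29 to 80 down, the lowest both without library 3. The cell cycle list turned to lower, past the threshold, with cells of another type's UMI left out (adjusted p = 0.0185) and without library 2 (adjusted p = 0.0245). With a library left out its adjusted p ran from 0.01785 (higher, without library 1) to 0.229 (higher, without library 3).

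In the CCR7 gate (54 up, 5 down) there were 7 up and 1 down with the DESeq2 Wald test, 8 down with no matching, 31 up and 9 down with cells that show a UMI of another cell type left out, 11 up and 3 down without shallow copies, and 7 up and 2 down without the low-depth clusters. A gate of at least 2 UMIs gave 0 up and 0 down (7 and 23 unadjusted; 439 genes tested), and thinned cells gave 0 up and 0 down (8 and 6 unadjusted). Leaving out a library gave 0 to 46 up and 0 to 7 down, 0 and 0 without library 1 (103 and 57 unadjusted) and 1 and 1 without library 3. With at least 2 UMIs, MT-ND3 turned to -0.26, MT-ATP6 to -0.036, MT-ND2 to -0.30 and MT-ND4 to -0.021, and in thinned cells EEF1B2 turned to -0.25 and MT-ATP6 to -0.049.

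In the interaction (0 up, 2 down by edgeR, 59 and 62 unadjusted) the DESeq2 Wald test gave 0 up and 1 down. There were 0 down with no low-count filter (218 unadjusted), no matching (120), another draw (55), cells with a UMI of another cell type left out (46), without shallow copies (45) and without the low-depth clusters (41). Leaving out a library gave 0 to 1 up and 0 to 2 down, 0 down without library 2 (82) and library 3 (52).

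Without the library block, edgeR gave 0 up and 0 down in the FOXP3 gate (69 and 74 unadjusted), 2 up and 0 down in the HLA-DRA gate (66 and 72), 0 and 0 in the CCR7 gate (14 and 19), and 0 up and 0 down in the interaction (44 and 37); the library differences then enter the error.

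With an estimated correlation, 0 lists passed in each of the 4 comparisons, against 6, 6, 4 and 1 with the preset one. For FOXP3, leaving out a library gave 2 to 7 lists, 2 without library 2. For the interaction, 4 lists passed with no matching, 2 with cells that show a UMI of another cell type left out, 0 without the low-depth clusters, and 0 to 1 with a library left out, 0 without library 2.

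The Treg-like share (35.4%) was 19.8% at doubled resolution and 30.9% with doublets kept. With no centring it was 38.5%, with an SD over libraries of 18.0 against 4.22 in the main result. The cycling-like share (2.01%) was 0.639% without shallow copies and 2.38% at doubled resolution. The cytotoxic T-like share (15.4%) was 7.44% at doubled resolution, and the unnamed share (47.2%) was 68.4% at doubled resolution, 59.5% with no centring, 67.1% with doublets kept and 68.1% after reclustering without copies. A class not named under an alternative has no value there. Median UMIs per cell (3172) were 2153 with no filter and 4312 with the stricter one. Median genes (1108) were 854.5 with no filter, 1007 with no filter and no shallow copies, and 1359 with the stricter filter. The difference in HLA-DRA share (0.591 points) was 9.37 with no thinning, 2.24 at 750 UMIs and -0.199 without shallow copies, and that in CCR7 share (-0.126) was 6.49 with no thinning, 2.22 at 750 UMIs and -2.01 to 2.76 with a library left out.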

Other observations

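The IL2RA and TRDC gates and all tests in this part were chosen only after the results were seen. Cells with a UMI of IL2RA, which encodes CD25 itself, were compared with cells without one in a single draw. By edgeR 20 rose and 59 fell of 6164 tested (540 at an unadjusted p under 0.05), with 202, 135 and 318 cells per class in libraries 1 to 3. Genes of dividing cells rose, HMGB2 by a log2 fold change of 0.68 (SE 0.09, adjusted p = 6.85e-11), TYMS by 1.65 (SE 0.37), MKI67 by 1.34 (SE 0.32), STMN1 by 0.58 (SE 0.13), TUBA1B by 0.39 (SE 0.10) and PTTG1 by 0.97 (SE 0.19). MKI67 and TYMS stood at 413 and 307 CPM in the cycling-like cluster 6 against 2.84 and 3.49 CPM in the other cells. Of its 46 cells 34 were shallow copies, and the others had a median of 15324 UMIs. The rises of MKI67 and TYMS may thus rest on few deep cells, which was not tested. RGS1 (0.74, SE 0.15) and MIR4435-2HG (0.73, SE 0.15) rose too. IL7R was lower by -0.63 (SE 0.08, adjusted p = 3.83e-10, lower in 3 of 3 libraries). Lower too were the cytotoxic genes GZMA (-0.84, SE 0.24), GZMK (-0.99, SE 0.29) and CCL5 (-0.72, SE 0.21), the transcription factor gene JUN (-0.67, SE 0.19), PLAC8 (-0.58, SE 0.13) and ATM (-0.46, SE 0.12). Without shallow copies 30 rose and 81 fell, and with cells that show a UMI of another cell type left out 17 rose and 67 fell. The 1 real split of the sums called 79 genes and the highest of the others 6, and 10 splits are too few for a share under 0.05.

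By camera in the IL2RA gate, cell cycle genes were higher (adjusted p = 6.51e-07, 5 of 7 over all genes and 6 adjusted over the list alone), cytotoxic and Th1 genes lower (0.000723, 3 of 5) and ribosomal protein genes lower (3.71e-07, 39 of 86, and 70 adjusted over the list alone). These had adjusted p = 0.405, adjusted p = 0.405 and adjusted p = 0.469 with an estimated correlation. Effector memory (0.0423, higher), naive and central memory (0.0423, lower) and MHC class II genes (0.0423, higher) passed too. These had adjusted p = 0.405, adjusted p = 0.405 and adjusted p = 0.469 with an estimated correlation. Mitochondrial (0.0667), homing receptor (0.220), Th2 and Th17 (0.330), immediate early and stress (0.376), interferon response (0.657) and glycolysis genes (0.813) did not pass. Of the markers of other cell types, AIF1 of monocytes (-0.74, SE 0.23, adjusted p = 0.0808, past the threshold adjusted over the list alone) and CD79B of B cells (0.09, SE 0.19, adjusted p = 0.951) were tested. A hypothesis is that IL2RA detection may separate Treg from other cells of the sort better than FOXP3 detection does. Treg core genes were higher (adjusted p = 0.000379) and conventional T genes lower (adjusted p = 0.000138, IL7R alone over all genes and 3 adjusted over the list alone). With an estimated correlation these were adjusted p = 0.405 and adjusted p = 0.445. Besides, 0 Treg core genes passed over all genes by edgeR (2 adjusted over the list alone). No test compared the gates directly, and the question stays open.

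Cells with a UMI of TRDC, a gene with its highest share in the cytotoxic T-like cluster 3 (10.6 ± 4.40% against 2.50 ± 1.42% in cluster 0), had 9 genes higher and 4 lower of 1168 tested by edgeR (77 at an unadjusted p under 0.05). The classes held 33, 10 and 29 cells each and 38261 to 113770 UMIs per sum. KLRB1 rose by 2.32 (SE 0.20, adjusted p = 2.29e-27), CTSW by 3.31 (SE 0.62), LST1 by 3.86 (SE 0.79, 34 UMIs against 2), DDIT4 by 1.48 (SE 0.34), NFKBIA by 1.18 (SE 0.34), IL7R by 0.73 (SE 0.21) and LTB by 0.68 (SE 0.11). Without shallow copies 3 rose and 1 fell, and with cells that show a UMI of another cell type left out 2 rose and 1 fell. IL7R then stood at 0.71 (adjusted p = 0.426) and 0.26 (adjusted p = 0.990). CD3D (-0.70, SE 0.17), ATP2B1 (-1.51, SE 0.39) and TMSB4X (-0.24, SE 0.06) were lower. No list passed (smallest adjusted p = 0.205, naive and central memory, lower), and no marker of another cell type had enough counts. The 1 real split called 13 genes and the highest of the others 3, and 10 splits are too few for a share under 0.05. A hypothesis is that gamma delta or innate-like lymphocytes may be among the sorted cells. TRAC, the constant gene of the alpha chain, was lower with TRDC (log2 fold change -0.54, SE 0.13, adjusted p = 0.00825), but it stood at -0.47 (adjusted p = 0.196) without shallow copies and at -0.17 (adjusted p = 0.990) with cells that show a UMI of another cell type left out. This stays open.

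Copies and originals were spread unevenly over the libraries. Library 2 held the originals of 144 copies in library 1 and of 75 in library 3, and library 1 those of 117 in library 2 and of 64 in library 3. Another 15 in library 1 and 11 in library 2 had their original in library 3.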
